A study of Macaca fascicularis with 80 samples.

How the data were processed

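Whole blood of 8 cynomolgus macaques, 4 female and 4 male, was collected into PAXgene tubes on 10 days and profiled by bulk RNA sequencing, which gave 80 libraries, 1 per animal and day. The animals received IL-15 complexed with IL-15 receptor alpha (IL-15/IL-15Ra) at 5 µg/kg on day 0, 10 µg/kg on day 3 and 15 µg/kg on day 7. Per the labels' protocols, RNA was isolated with the RNAdvance Blood kit and libraries were made with KAPA HyperPrep mRNA reagents. The samples of days 3 and 7 carry the preceding dose in the labels and were read, though the labels do not say so, as taken before that day's dose. Blood of day 0 carries a dose of 0 and was the only baseline, and no undosed animals were analysed.

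The authors deposited gene counts, that is, whole numbers of reads per gene that are not normalized, in 2 tables of the same 80 libraries. Aligner, counting program, genome build and strand setting are not given in the sources used here. The main table lists 38550 genes and the second one 35432 genes under other identifiers. Identifiers of neither table are paired with gene names in the files, and none of them matched the gene table used for names (assembly T2T-MFA8v1.1 of Macaca fascicularis), where 0 identifiers were found. The 27 gene lists fixed before the data were examined, the tests of those lists and the alternative without haemoglobin genes therefore could not be run, and gene products are not named. Only 4 identifiers are printed, 2 that rose and 2 that fell. They were chosen by the rule fixed beforehand without its demand for a gene symbol, as the genes with the largest and smallest log2 fold change on day 1 among those with an adjusted p under 0.05, a mean of at least 2 log2 CPM (counts scaled to library size) and the same direction in all 8 animals. The rule as fixed would have named further genes for each comparison and a list of chosen symbols. Reads shared between near-identical genes could not be traced, so the values of single identifiers carry that uncertainty.

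Library totals ran from 17.09 to 80.22 M counts (M, mega; median 24.3 M) in the main table and from 17.36 to 81.02 M in the second. Genes were kept with edgeR's filterByExpr grouped by day over all 80 libraries, which left 16054 genes (41.6%). Scaling factors were trimmed means of M-values (TMM) over all 80 libraries. Each pair of days was fitted on its own 16 libraries with animal as a block, with edgeR 4.0.16 (glmQLFit and glmQLFTest, trended dispersion) in R 4.3.3. Genes with a Benjamini-Hochberg adjusted p under 0.05 are called changed. Differences between doses in the 24 h response used the 32 libraries of 4 days, and the sex-by-day test used the 32 libraries of days 0, 1, 4 and 8 with 3 interaction terms. Log2 CPM values had a prior count of 2.

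Animal numbers in the labels identify the same animal across days, which gives the pairing. Deviations from the day means, correlated over genes between days, had a median r of 0.44 for libraries of the same animal (lowest -0.14) and of -0.06 for libraries of different animals. All 80 libraries correlated best with a library of their own animal. No pair of libraries within a day agreed within counting noise, since the smallest chi-square per degree of freedom was 29.9. All 72 later libraries fell on the labelled side for genes that separated the sexes at day 0. Column names carry sequencing tags. Of the 80 libraries, 71 share 1 run and library tag, 8 carry another run tag (3 of day 10 and 5 of day 14), and 1 of day 7 carries another library tag.

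Gene sets were followed over time without reusing the animal that was scored. For each animal, the genes called on day 1 or on day 21 were chosen in the other 7 animals, and their mean log2 change from day 0 was measured in the animal left out. Means over 8 animals were tested with an exact two-sided sign-flip permutation test of 256 flips, whose smallest p is 0.00781, with Benjamini-Hochberg adjustment within each family of tests (36 scores, 36 steps between days, 21 means of dose-called sets by day, 10 such means by dose, 4 dose differences and 3 correlations). The sets stayed fixed under the flips, although each animal helped choose the sets scored in the other 7. For scores in animals left out, the p is therefore approximate. Sets called between days 3 and 4 or between days 7 and 8 were measured on the days not used to choose them. The distance of a library from the animal's own day 0 is the root mean square (RMS) of its log2 changes over all 16054 genes. These scores, distances and correlations were chosen after the data had been examined.

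The procedures were tested on simulated data, with counts drawn from the real libraries' means and 200 of the 16054 genes changed. The changed genes were drawn only from those with an average above 2 log2 CPM. The spread followed the dispersion trend, and a changed gene changed alike in all animals. The shares recovered hold for such genes and not for all genes tested. For day 1 versus day 0, edgeR recovered 94.0% of the genes changed 1.5-fold and 100% of those changed 2-fold. For day 4 versus day 0 it recovered 26.9% at 1.5-fold and 85.1% at 2-fold. For day 8 versus day 7 the shares were 31.3% and 94.0%, and for day 21 versus day 0 they were 85.1% and 100%. The difference between the second and the first dose was recovered for 14.9% of genes at 1.5-fold and 82.1% at 2-fold. The sex-by-day test recovered 1.5% at 1.5-fold, 16.4% at 2-fold and 93.9% at 4-fold. In the day 1 simulation, 14 of 210 genes called by edgeR and 26 of 225 called by DESeq2 had not been changed.

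The alternatives fixed before the data were examined were RLE and upper-quartile factors, no low-count filter, a stricter filter (1 CPM in 40 libraries), DESeq2 1.42.0, no animal block, 1 fit over all 80 libraries, the second count table and leaving out each animal. Alternatives added afterwards were library totals without scaling factors, thinning every library to 17.09 M counts, leaving out libraries over 40 M counts, pairs within the shared run and library tag, terms for these tags, limma 3.58.1 voom with sample weights, a prior count of 0.5 for the gene-set scores, and leaving out the day 4 library of animal 39102.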

Results

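The study followed whole-blood gene expression in 8 cynomolgus macaques given escalating doses of IL-15/IL-15Ra, a complex of the cytokine interleukin 15 with its receptor alpha chain, which stimulates natural killer and CD8 T cells. Animals were dosed at 5 µg/kg on day 0, 10 µg/kg on day 3 and 15 µg/kg on day 7 and were bled on days 0, 1, 3, 4, 7, 8, 10, 14, 17 and 21. Each day had 8 libraries, 1 from each of 4 females and 4 males. Libraries held 17.09 M to 80.22 M counts (M, mega). Median totals per day ran from 21.1 M on day 14 to 48.2 M on day 10, where 4 libraries exceeded 40 M. On day 8, 3 libraries exceeded 40 M, all from males, and on day 7 this held for 1 library. The files do not pair gene identifiers with names, so changes are described by gene set and time course, with 4 identifiers as examples. Dose, order of dosing and elapsed time rise together in this design and cannot be separated.

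**Figure D1:**
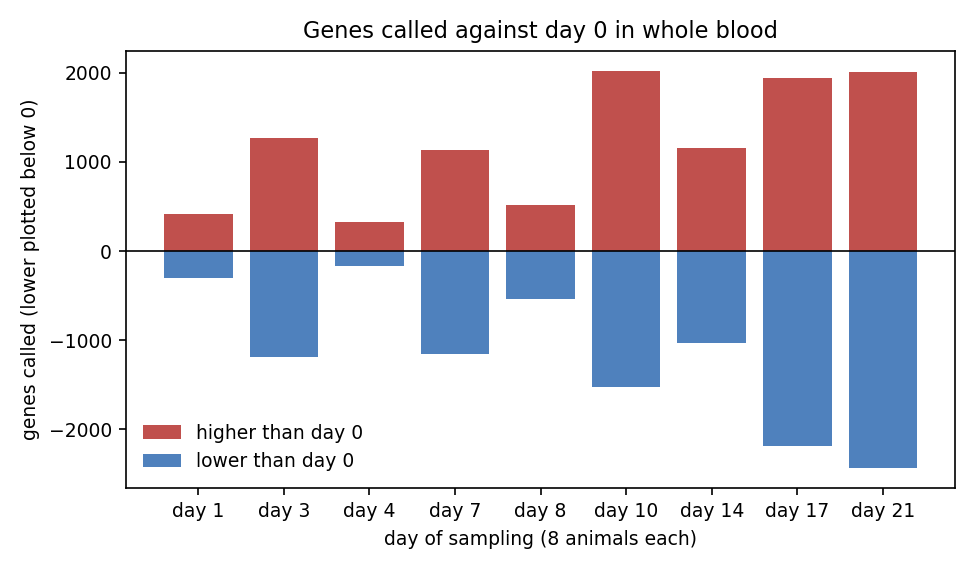
Number of genes called against day 0 (edgeR, adjusted p under 0.05, 16054 genes tested, 8 animals) on each later day, with genes higher than day 0 plotted above 0 and genes lower than day 0 plotted below it. In these fits of 16 libraries, day 21 had 2011 genes higher and 2434 lower, whereas 1 fit over all 80 libraries gave another order, with 4420 genes on day 8, 5402 on day 14 and 2896 on day 21.

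The first comparison asked what had changed in blood 24 h after the first dose. Between day 0 and day 1, 419 genes rose and 298 fell, together 717 genes or 4.47% of those tested. Large changes were mostly decreases, with 80 genes down and 28 up by more than 2-fold. ENSMFAG00000040797 fell the most under the naming rule, by 2.87 on the log2 scale (SE 0.46, adjusted p = 0.003, lower in 8 of 8 animals). Its level went from 4.60 ± 0.49 log2 CPM (SD, n = 8) to 1.57 ± 1.69. ENSMFAG00000044133 fell by 2.63 (SE 0.45, adjusted p = 0.0039, lower in 8 of 8 animals). ENSMFAG00000042017 rose by 1.84 (SE 0.28, adjusted p = 0.0024) and ENSMFAG00000044266 by 1.58 (SE 0.22, adjusted p = 0.0014), both in 8 of 8 animals. Because the 4 were chosen for a call, a large change and 1 direction in all 8 animals on day 1, these day 1 values restate that choice. All 4 calls rested on the pairing, since without the animal block their adjusted p lay between 0.14 and 0.67. The calls of the rising pair were also lost in 1 fit over all 80 libraries (adjusted p = 0.1 and 0.087). The count of 717 became 455 without animal 39090 and 465 without animal 39103, and with library totals in place of TMM factors 348 genes rose and 400 fell. One fit over all 80 libraries called 46 up and 73 down.

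On day 3, before the second dose, 1270 genes were higher than on day 0 and 1194 lower. Of the 419 genes called up on day 1, 237 were also called up on day 3, whereas 33.1 would be shared by independent lists. Of the 298 called down, 107 were also called down (22.2 for independent lists) and 5 were called up. The 2 comparisons share their day 0 libraries, which raises such overlaps. Fold changes of days 1 and 3 correlated across genes at r = 0.47. This was no higher than the 0.50 of simulated unchanged days that shared a day 0 redrawn from the real day 0 counts. Every such simulation, for later days too, took its spread from days 0 and 1. The covariance was 0.0626 against 0.0231 in the simulation. With day 1 measured in 4 animals and day 3 in the other 4, which share no libraries, the correlation averaged 0.19 over 70 splits. The log2 differences of ENSMFAG00000040797 and ENSMFAG00000044133 from day 0 were 0.06 and -0.09 (SE 0.24 and 0.23, adjusted p = 0.91 and 0.86). ENSMFAG00000042017 was still 1.52 higher (SE 0.26, adjusted p = 0.0024). The count of 2464 became 1545 without animal 39103, and without the animal block 201 genes were higher and 74 lower.

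Genes chosen on day 1 in 7 animals were followed in the animal left out. The sets held 263 to 382 genes that rose and 185 to 265 that fell. In the animals left out, the falling set was lower than day 0 by a mean log2 change of -0.75 ± 0.35 (SD, n = 8) on day 1, -0.72 ± 0.30 on day 4 and -0.63 ± 0.31 on day 8, each in 8 of 8 animals (exact permutation adjusted p = 0.0201 for each). It had partly recovered on day 3, at -0.33 ± 0.24 (adjusted p = 0.0352 by the exact test), and stood at 0.13 ± 0.19 on day 7 and -0.02 ± 0.16 on day 10 (exact adjusted p = 0.159 and 0.819). Each step of this course, down after every dose and up before the next, passed the exact test, at an adjusted p of 0.0216 for the 5 steps up to day 8 and 0.0352 for the rise from day 8 to day 10. The rising set was 0.47 ± 0.14 above day 0 on day 1, 0.42 ± 0.13 on day 3, 0.72 ± 0.27 on day 4, 0.77 ± 0.29 on day 8 and 0.54 ± 0.21 on day 10, in 8 of 8 animals each time (exact adjusted p = 0.0201 for each). It stood at 0.17 ± 0.34 on day 7, with 5 of 8 animals above day 0, and at 0.56 ± 0.50 on day 14, with 7 of 8 above (exact adjusted p = 0.304 and 0.0469). It was at 0.04 ± 0.13 and 0.07 ± 0.15 on days 17 and 21 (exact adjusted p = 0.533 and 0.304). Scaling mattered for the last values, which were 0.13 and 0.16 with library totals (unadjusted exact p = 0.0391 and 0.0156) and 0.10 on day 21 with upper-quartile factors (unadjusted exact p = 0.0391).

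**Figure D2:**
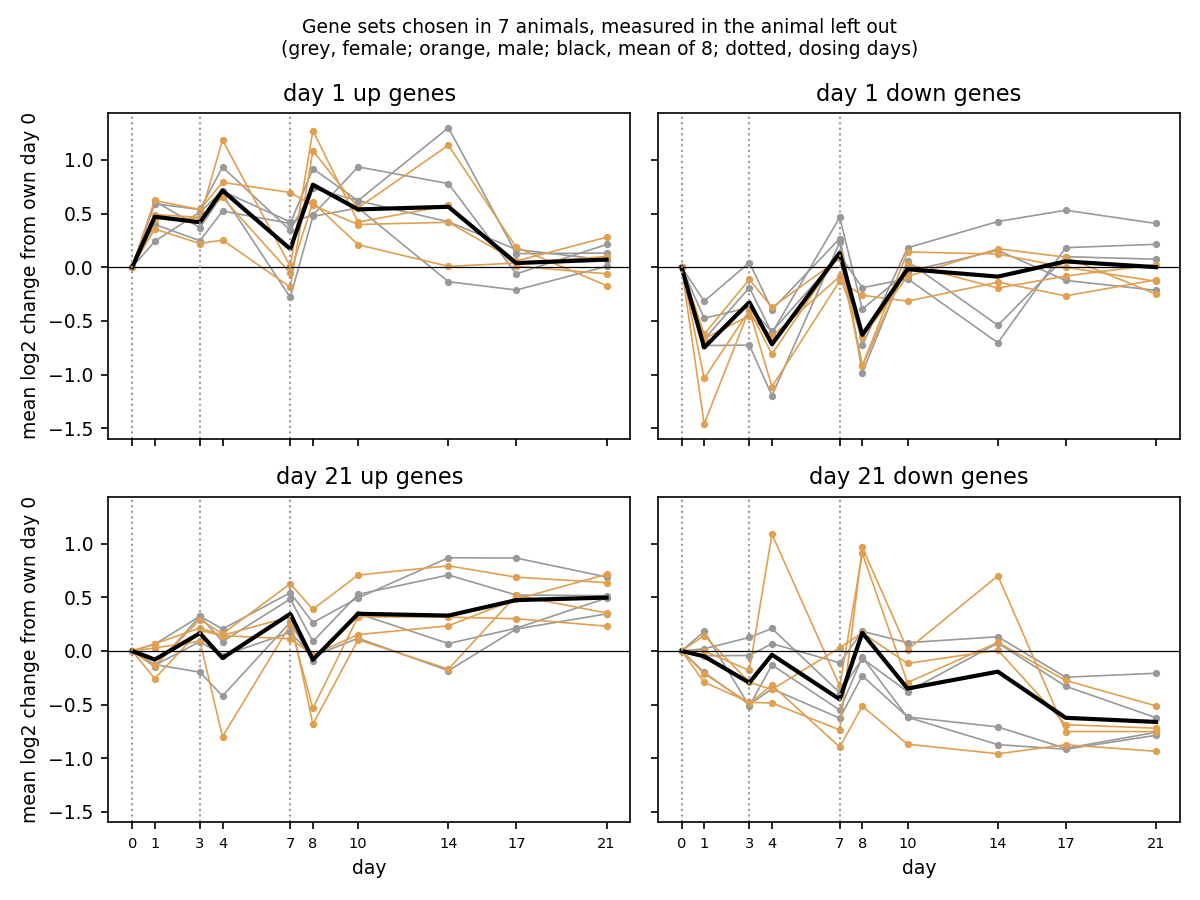
Mean log2 change from the animal's own day 0 (vertical axis) by day (horizontal axis) for 4 gene sets, each chosen in 7 animals and measured in the animal left out; thin lines are animals, the black line is the mean of 8, and dotted lines mark dosing days. The day 1 down genes fell after each dose, to -0.75, -0.72 and -0.63, and the day 21 genes reached 0.50 and -0.66 on day 21.

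The second dose, 10 µg/kg on day 3, was assessed by comparing day 4 with day 3. No gene was called up and 29 were called down, 19 of them by more than 2-fold, with 1762 genes at an unadjusted p under 0.05. Of these 29 genes, 23 had also been called down between days 0 and 1, where independent lists would share 0.538, and 28 were called down again between days 7 and 8. ENSMFAG00000040797 fell by 1.52 (SE 0.25, adjusted p = 0.045) in 8 of 8 animals, while the 1.39 fall of ENSMFAG00000044133 (SE 0.24, adjusted p = 0.053) missed the threshold, also with 8 of 8 animals lower. The first of these calls was lost with library totals (adjusted p = 0.05), in the fit over all 80 libraries (adjusted p = 0.099), without the block (adjusted p = 0.66) and without any 1 of animals 39090, 39095, 39097, 39098, 39100 and 39103 (adjusted p 0.055 to 0.18). The second passed without the day 4 library of animal 39102 (adjusted p = 0.0043). The count of 29 depended on single animals. It was 183 (41 up and 142 down) without the day 4 library of animal 39102 and 0 without any 1 of animals 39090, 39095, 39098, 39100 and 39103, and DESeq2 called 260 (35 up and 225 down). Against day 0, day 4 had 325 genes higher and 164 lower. That count was 1819 without animal 39102 and 111 to 185 without any 1 of animals 39090, 39095, 39097, 39098, 39100 and 39103. With library totals, 141 were higher and 152 lower. Day 4 differed from day 1 in 1 gene, higher by 1.72 on day 4 and outside the 4 identifiers printed, with 1136 genes at an unadjusted p under 0.05, and in 133 genes by DESeq2. Without the 39102 library the count was 20, and 0 without any 1 of animals 39090, 39097, 39098, 39100 and 39103.

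The 29 genes that fell after the second dose were then followed on days not used to choose them. They were below day 0 by a mean of -1.30 ± 0.85 (SD, n = 8) on day 1 and -1.06 ± 0.77 on day 8, in 8 of 8 animals. They stood above day 0 by 0.89 ± 0.37 on day 7 in 8 of 8 animals and by 0.74 ± 0.46 on day 10 in 7 of 8 animals. They were still 0.66 ± 0.29 and 0.69 ± 0.19 above day 0 on days 17 and 21, in 8 of 8 animals. Exact sign-flip permutation tests gave an adjusted p of 0.0164 for each of these days, except 0.0273 for day 10. On day 14 the mean of 0.23 ± 0.71 did not differ from day 0 by the exact test (adjusted p = 0.513). ENSMFAG00000040797 showed this course, at 1.20 above day 0 on day 7 (SE 0.12, adjusted p = 0.00046) and at a log2 difference of -2.04 on day 8 (SE 0.42, adjusted p = 0.025, lower in 7 of 8 animals).

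**Figure D3:**
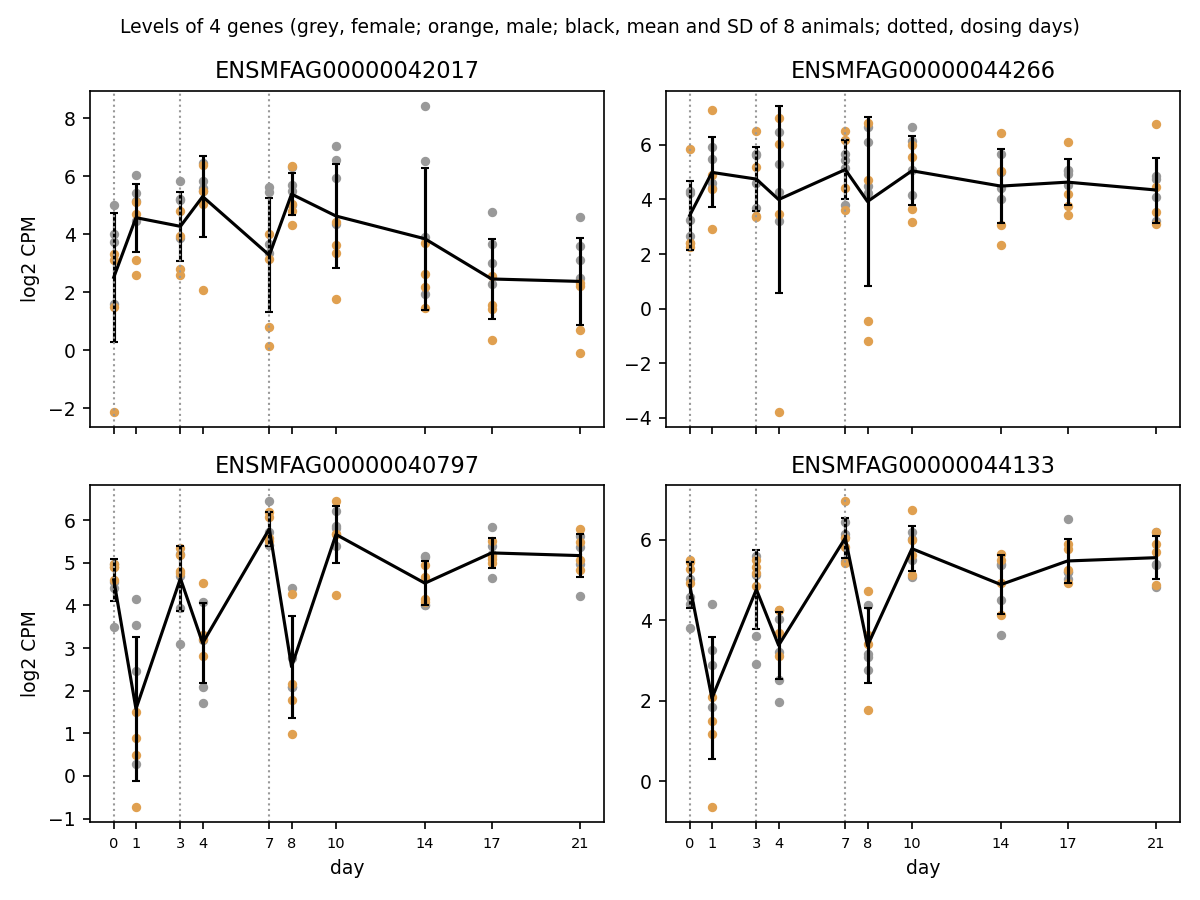
Log2 CPM (vertical axis) of the 4 identifiers by day (horizontal axis); points are the 8 animals, the black line joins the means, bars are SD, and dotted lines mark dosing days. ENSMFAG00000040797 went from a mean of 5.79 on day 7 to 2.56 on day 8, and ENSMFAG00000044133 from 6.05 to 3.37, and the lowest point of ENSMFAG00000044266, animal 39102 on day 4, is a count of 0.

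The third dose, 15 µg/kg on day 7, was followed by more calls in 24 h than the first or the second with all 8 animals. From day 7 to day 8, 964 genes rose and 1247 fell, and 697 of these changes exceeded 2-fold. ENSMFAG00000040797 fell by 3.25 (SE 0.48, adjusted p = 0.011) and ENSMFAG00000044133 fell by 2.65 (SE 0.45, adjusted p = 0.015, or 0.052 without animal 39095), each in 8 of 8 animals. ENSMFAG00000042017 was higher by 1.89 in 8 of 8 animals and missed the threshold (SE 0.62, adjusted p = 0.062, or 0.01 by DESeq2), and ENSMFAG00000044266 changed by -0.82 (SE 0.71, adjusted p = 0.42), with 4 animals in each direction. Smallest adjusted p values were near the threshold in this comparison (minimum 0.0106), and the count of 2211 depended on single animals. It was 145 without animal 39095, 224 without 39098, 319 without 39102, 513 without 39090, 604 without 39100 and 1468 without 39097. The day 7 library of animal 39095 has its own library tag, and within the shared tag 144 genes were called, 13 up and 131 down. That subset leaves out the same animal as the 145 above, so library tag and animal cannot be told apart. With library totals 602 rose and 4119 fell, with a median log2 change of all genes of -0.43 in place of -0.06. More genes rose than fell by DESeq2 (2478 and 2066), by limma voom with sample weights (1795 and 1517) and without libraries over 40 M counts (1836 and 1106). The last setting also left out animals 39097, 39102, 39103 and 39104, so depth and animals changed together. Against day 0, day 8 had 516 genes higher and 536 lower, or 390 and 667 with upper-quartile factors and 240 and 1849 with library totals. One fit over all 80 libraries called 4420 genes on day 8 and DESeq2 3138. More were higher than lower without the animal block (881 and 564) and without libraries over 40 M counts (332 and 184). That count of 1052 was 288 to 547 without any 1 of the animals except 39100, and 1360 without that animal. Day 8 differed from day 1 in 150 genes (77 higher and 73 lower, or 28 and 44 with upper-quartile factors and 12 and 22 without the low-count filter), but leaving out any 1 animal left 3 to 9. Other models gave more, with 398 genes without the animal block, 587 by limma voom, 1880 by DESeq2 and 3099 in the fit over all 80 libraries.

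Differences between doses in the 24 h response were tested directly. The response to the third dose differed from that to the first in 793 genes, 538 with a more positive and 255 with a more negative change (452 and 1468 with library totals). DESeq2 called 2133 genes, the fit over all 80 libraries 1237 and the fit without the animal block 0. Each omission of 1 animal moved this count by over 1.5 times. It was 0 without animal 39098 or 39102, 1 without 39104, 7 without 39100, 18 without 39090, 189 without 39097, 512 without 39095 and 1522 without 39103. The response to the second dose differed from the first in 0 genes by edgeR, with 1335 genes at an unadjusted p under 0.05, and in 23 genes by DESeq2. Mean changes of the 3 intervals, which share no libraries, were compared across genes, which are not independent replicates. The second and the third dose correlated at r = 0.65 (exact permutation adjusted p = 0.0468), or 0.41 without animal 39102. The first dose correlated with the second at r = 0.25 and with the third at r = 0.31 (exact adjusted p = 0.0704 and 0.0859).

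Genes called after a dose were measured after the other doses. The 298 genes that fell after the first dose changed by a mean of -0.38 ± 0.16 (SD, n = 8) after the second and -0.70 ± 0.34 after the third, lower in 8 of 8 animals each time (exact adjusted p = 0.013). The 419 that rose changed by 0.26 ± 0.18 after the second dose and 0.53 ± 0.44 after the third, in 7 of 8 animals (exact adjusted p = 0.0195 and 0.026). With library totals these became 0.09 and 0.16, neither past the threshold. Of the 298 falling genes, 158 were called down and 20 called up after the third dose, against 23.1 and 17.9 for independent lists. Of the 419 rising genes, 86 were called up and 2 called down, against 25.2 and 32.5. Conversely, the 964 genes that rose after the third dose changed by 0.02 ± 0.17 after the first, with 4 of 8 animals higher (exact adjusted p = 0.672), while the 1247 that fell changed by -0.31 ± 0.16 in 8 of 8 animals (exact adjusted p = 0.013).

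Day 7, before the third dose, and day 10, 3 days after it, were compared with day 0. On day 7, 1136 genes were higher and 1154 lower, a count that was 1242 without animal 39098, 1341 without 39104 and 1509 without 39100. On day 10, 2025 were higher and 1521 lower. With library totals the day 10 split was 1339 and 1543. Among the 5 animals with both libraries in the shared sequencing run, 2384 genes were called on day 10, and among the 4 animals without a library over 40 M counts, 544. The day 10 libraries with the other run tag came from males 39102, 39103 and 39104, and none exceeded 40 M counts. Run, depth and sex therefore changed together in these subsets. Of the 298 genes called down on day 1, 96 were called up on day 7 and 72 called down, where independent lists would share 21.1 and 21.4. Both comparisons use the same day 0 libraries, which lowers the first of these overlaps and raises the second. ENSMFAG00000042017, which had risen on day 1, was 4.01-fold above day 0 on day 10 (SE of log2 0.28, adjusted p = 0.00072) in 8 of 8 animals. ENSMFAG00000044133 was 0.92 above it on the log2 scale (SE 0.19, adjusted p = 0.0051).

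The later samples, 7 to 14 days after the last dose, still differed from day 0. On day 14, 1156 genes were higher and 1034 lower. On day 17 the counts were 1939 and 2183, and on day 21 they were 2011 and 2434, or 27.7% of the genes tested. Days 17 and 21 shared 3370 calls in the same direction and 0 in opposite directions, where independent lists would share 243 up and 331 down. Their fold changes correlated across genes at r = 0.88 against 0.49 in simulated unchanged days, with a covariance of 0.210 against 0.0223, and at 0.61 on average when the 2 days were measured in different sets of 4 animals. Day 1 and day 21 correlated at r = 0.16 with all animals, below the 0.50 of the simulation, with a covariance of 0.0263 against 0.0224, and at 0.00 between different sets of 4 animals (range -0.14 to 0.14). With library totals, 336 genes were higher and 1873 lower on day 14, 2848 and 1550 on day 17, and 2723 and 1839 on day 21. On day 14 the count of 2190 became 1171 without animal 39103, 1349 without 39102, 1354 without 39090 and 1429 without 39097. Among the 3 animals within the shared sequencing run, all male, it was 1148, with 805 genes higher and 343 lower. ENSMFAG00000044266 was 1.20 above day 0 on day 17 (SE 0.22, adjusted p = 0.003) and 0.93 on day 21 (SE 0.27, adjusted p = 0.018). Against day 0 it was also called on days 3, 7 and 10, but not on days 4, 8 and 14 (adjusted p = 0.54, 0.53 and 0.089 by edgeR). ENSMFAG00000042017 was at -0.33 on day 21 (SE 0.24, adjusted p = 0.35).

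Genes of the late profile were also followed in animals left out of choosing them. The sets held 1456 to 2166 genes higher on day 21 and 1969 to 2494 genes lower. The higher set reached 0.35 ± 0.18 (SD, n = 8) above day 0 on day 7, before the last dose, in 8 of 8 animals. It was at -0.08 ± 0.37 on day 8, at 0.35 ± 0.22 on day 10, and at 0.47 ± 0.23 and 0.50 ± 0.18 on days 17 and 21, in 8 of 8 animals on days 10, 17 and 21 (exact adjusted p = 0.0201 for days 7, 10, 17 and 21 and 0.635 for day 8). On day 14 it was at 0.33 ± 0.42, with 6 of 8 animals above day 0 (exact adjusted p = 0.134). With library totals the day 10 value was 0.30 and missed the threshold (unadjusted exact p = 0.0547). The lower set was at -0.45 ± 0.31 on day 7, 0.17 ± 0.52 on day 8, and -0.62 ± 0.29 and -0.66 ± 0.22 on days 17 and 21 (exact adjusted p = 0.0352, 0.53, 0.0201 and 0.0201). On days 10 and 14 it was at -0.35 ± 0.33 and -0.19 ± 0.59, with 2 and 5 of 8 animals above day 0 (exact adjusted p = 0.0592 and 0.533).

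Sex was compared at baseline and in the response. At day 0, 14 genes differed between the sexes, 2 higher in females and 12 higher in males, with a median absolute log2 difference of 9.01. DESeq2 called 145. The response over days 1, 4 and 8 differed by sex in 0 genes by edgeR, with 1028 genes at an unadjusted p under 0.05, and in 55 by DESeq2. With 4 animals of each sex, differences of 2-fold or less were mostly below what this test could detect. On day 8 the distance from day 0 was 1.09 ± 0.26 in males and 0.79 ± 0.05 in females (SD, n = 4 each, exact permutation p = 0.0571, adjusted p = 0.514 over 9 days, smallest possible p 0.0286). The 3 males whose day 8 libraries exceeded 40 M counts lay at 1.34, 1.29 and 0.93, and the other male at 0.82. Sex and the deeper libraries therefore overlap in this comparison. With every library thinned to 17.09 M counts, the SD of the day 8 distances was still 0.24 and the largest were 1.30 and 1.26. These values argue against count depth as the source of that spread, but the sexes were not compared again on thinned counts.

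Distances from day 0 varied most between animals on days 4, 8 and 14. The RMS distance from own day 0 had an SD between animals of 0.28 on day 4, 0.24 on day 8 and 0.14 on day 14, against 0.05 to 0.09 on the other days. The day 4 value rested on animal 39102, without which it was 0.08. Mean distances were 0.71 ± 0.06 (SD, n = 8) on day 1, 0.94 ± 0.24 on day 8, 1.06 ± 0.14 on day 14 and 0.80 ± 0.05 on day 21. TMM factors were lowest on the same days, with means of 0.951 ± 0.159 on day 4, 0.841 ± 0.132 on day 8 and 0.874 ± 0.170 on day 14, against 1.043 ± 0.090 on day 0.

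**Figure D4:**
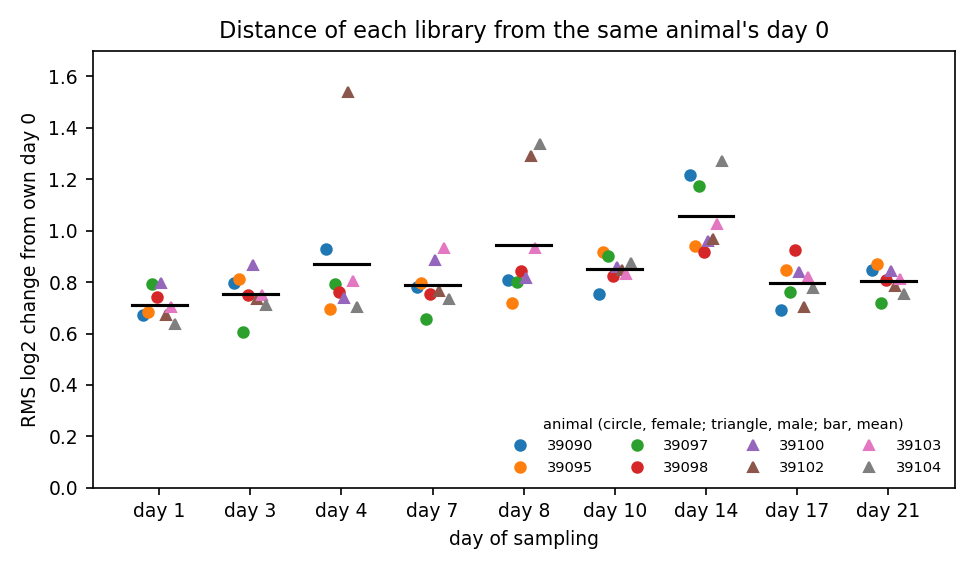
RMS log2 change of each library from the same animal's day 0 (vertical axis) by day of sampling (horizontal axis); points are the 8 animals and bars the means. Animal 39102 lay at 1.54 on day 4, where the next animal was at 0.93, and animals 39104 and 39102 lay at 1.34 and 1.29 on day 8.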

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

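The tests of explanations in this part were chosen after the results were seen, except the depth and abundant-gene tests of the distances, whose outcome was stated beforehand. The fit over all 80 libraries was planned as an alternative, and its use to weigh the spread was chosen afterwards. Of 87 groups of 8 values, 8 held a library far from the others, where chance gives about 4.4. On day 0, animal 39090 had 30.4 M counts and the next library 24.9 M. On day 3, animal 39097 had 36.2 M against 26.6 M, and on day 7 it had 51.4 M against 25.4 M. On day 10, the 50 most counted genes took 20.8% of the counts of animal 39097 and at most 17.0% elsewhere. On day 3, the genes higher on day 21 stood at -0.20 in animal 39090, with the nearest other at 0.09. The third dose differed from the first in 793 genes. The genes that fell on day 1 had a log2 change 0.36 higher after the second than after the first dose (a smaller fall in 7 of 8 animals, exact permutation p = 0.0156), which missed the threshold after adjustment (adjusted p = 0.0625).

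The day 4 library of animal 39102 lay far from the others on 3 measures, on 1 of the 3 days (4, 8 and 14) when distances varied most between animals (without this animal the day 4 SD was 0.08 in place of 0.28): its distance from own day 0 was 1.54 with the next at 0.93, its score for the genes lower on day 21 was 1.09 with the next at 0.21, and ENSMFAG00000044266 changed by -7.18 from day 3 to day 4 with the next at -0.46, where the library held 0 counts of the gene, so that the size of this value depends on the prior count. An exchange of libraries between animals is argued against, since 80 of 80 libraries lay nearest to another day of their own animal. Depth is argued against as well, since with every library thinned to 17.09 M counts the SD of the distances was 0.27 on day 4, 0.24 on day 8 and 0.14 on day 14, with at most 0.08 on other days. A few abundant genes stay open, because removing the 157 genes that were among the 50 most counted of any library left the rounded mean distances of all 9 days as they were (SD 0.23 on day 8) and so tested nothing, while the 50 most counted genes took 20.4% of the counts of animal 39102 on day 4 and 14.3% on day 3. An exchange of days within 1 animal, RNA quality, a shift in blood cell make-up and an individual response to the drug remain open, and no biological explanation other than sex was tested (day 8 distance by sex, exact p = 0.0571).

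Most genes were called against day 0 on days 17 and 21, after dosing had ended. With 1 estimate of the spread for all days, day 21 called 2896 genes and day 17 called 2404, against 3247 to 5402 on days 8, 10 and 14, when the median SD between animals was 0.44 to 0.65 (0.38 on day 21), so a smaller spread between animals may account for the excess over those days. It is argued against for the excess over days 1 and 3, which called at most 1118 genes in that fit and had a median SD of 0.36 and 0.37, and it stays open for days 4 and 7, with 1515 and 2109 genes there. Depth is argued against, since thinned libraries still gave 4432 genes on day 21 and 3390 on day 10. Elapsed time and repeated bleeding cannot be told apart from the drug, because 0 libraries came from undosed animals after day 0.

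Few genes were called 24 h after the second dose, 29 against 717 after the first. A single wide library is not the whole cause, since 183 genes were called without the day 4 library of animal 39102. A candidate explanation is that first-dose changes were still present when the second dose was given: the genes that fell on day 1 stood at -0.33 on day 3 and reached -0.72 on day 4, close to the -0.75 of day 1. It would not cover the 2 falling identifiers printed, which differed from day 0 by 0.06 and -0.09 on day 3. The RMS over genes of the mean log2 change was 0.37 from day 3 to day 4 and 0.34 from day 0 to day 1. The median SD between animals was 0.54 and 0.36, so the spread was wider after the second dose. In 1 fit over all 80 libraries, the second dose still gave fewer calls than the first. Whether their fall was smaller after the second dose is open (0.36, as above). Dose and order of dosing are confounded and stay open.

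Chance was tested by exchanging the 2 days compared within randomly drawn animals, with 40 exchanges drawn, the real one included. In each comparison of days with calls, 1 of 40 splits, the real one, gave as many genes, which is the smallest share these splits can give and was not adjusted for the number of comparisons. Such a share goes against chance for the 9 comparisons with day 0 and for day 8 versus day 7 but cannot exclude it. Other splits came near the real count for days 3 and 14, and day 8 versus day 7 gave 145 genes without animal 39095. Chance is left open for the other 4 because their counts were less stable, not because their splits differed. Every other split gave 0 genes there. The count came to 0 without some single animals (day 4 versus day 3, day 4 versus day 1, and the third against the first dose) or to 3 to 9 without any 1 (day 8 versus day 1). The real count and the highest other split were 717 and 7 for day 1, 2464 and 1850 for day 3, 489 and 0 for day 4, 2290 and 0 for day 7, 1052 and 1 for day 8, 3546 and 463 for day 10, 2190 and 1806 for day 14, 4122 and 1825 for day 17, and 4445 and 2233 for day 21. The pairs were 29 and 0 for day 4 versus day 3, 2211 and 0 for day 8 versus day 7, 1 and 0 for day 4 versus day 1, 150 and 0 for day 8 versus day 1, and 793 and 0 for the third against the first dose. Highest other splits for days 3, 17 and 21 exchanged a single animal or, equivalently, all but 1, and that for day 14 exchanged 3 of the 5 animals with another run tag, where 1148 genes were called within the shared run. For the second against the first dose, the count of 0 was matched by 40 of 40 splits, and the sex-by-day count of 0 by 35 of 35 splits of the animals into 4 and 4, as any count of 0 must be, so the splits say nothing about either. The 14 genes differing by sex at day 0 were reached by 1 of 35 splits, with 1 gene as the highest other.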

How the results depend on the processing

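Library totals, thinning, depth limits, run settings, voom, the omission of the day 4 library of animal 39102 and that of each animal for distances and scores were added after the data were examined. All counts are of genes called. The cause of a change was not tested unless stated. The list tests and the alternative without haemoglobin genes were not run, because identifiers could not be matched to names. Counts for day 4 versus day 1 (1 gene) were too small for a stable ratio.

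Most scaling and filtering settings changed few counts by over 1.5 times, but library totals did so for 6 of 17 and no low-count filter for 5 of 17. RLE factors did so for 1 of 17 results (day 4 versus day 1, 2 genes), the second count table for 1 of 16 (the same, 3 genes) and thinning for 0 of 17. Upper-quartile factors gave 45 for day 4 versus day 3 and 72 for day 8 versus day 1. Library totals gave 293 for day 4, 2089 for day 8, 0 for day 4 versus day 3, 13 for day 8 versus day 1, 4721 for day 8 versus day 7 and 1920 for the third against the first dose. They moved the median log2 change of all genes by up to -0.366 (day 8 versus day 7), so changes there are relative to that shift. Without the filter, the counts were 1417 for day 1, 68 for day 4 versus day 3, 14 for day 4 versus day 1, 34 for day 8 versus day 1 and 312 for the third against the first dose. The stricter filter gave 0 for day 4 versus day 1 and 1219 for the third against the first dose.

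Other tests called more genes. DESeq2 gave 1218 for day 1, 1600 for day 4, 3138 for day 8, 3926 for day 14, 260 for day 4 versus day 3, 4544 for day 8 versus day 7, 133 for day 4 versus day 1, 1880 for day 8 versus day 1, 23 for the second and 2133 for the third against the first dose, 55 for sex by day and 145 for sex at day 0. Voom with sample weights gave 2394 for day 4, 1724 for day 8, 245 for day 4 versus day 3, 32 for day 4 versus day 1 and 587 for day 8 versus day 1. It was run on comparisons of 2 groups only.

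The pairing by animal carried much of the power. Without the animal block, the counts were 10 for day 1, 275 for day 3, 204 for day 4, 622 for day 7, 1987 for day 10, 1718 for day 17, 1939 for day 21, 0 for day 4 versus day 3, 700 for day 8 versus day 7, 2 for day 4 versus day 1, 398 for day 8 versus day 1 and 0 for the third against the first dose, and no other count moved by over 1.5 times. One fit over all 80 libraries, which shares the spread between quiet and variable days, gave 119 for day 1, 1118 for day 3, 1515 for day 4, 4420 for day 8, 5402 for day 14, 2404 for day 17, 2896 for day 21, 9 for day 4 versus day 3, 5410 for day 8 versus day 7, 10 for day 4 versus day 1, 3099 for day 8 versus day 1 and 1237 for the third against the first dose. Run and library-tag terms in that fit gave 4544 for day 14 and 5121 for day 8 versus day 7. Pairs within the shared run and library tag gave 1148 for day 14 (3 animals) and 144 for day 8 versus day 7 (7 animals). The second of these left out only animal 39095, by its library tag and not its run. It therefore repeats the omission of that animal (145 genes).

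Without libraries over 40 M counts, fewer animals remained and the counts were 516 for day 8 (5 animals), 544 for day 10 (4 animals), 25 for day 8 versus day 1 and 364 for the third against the first dose. Without the day 4 library of animal 39102 the counts were 1825 for day 4, 183 for day 4 versus day 3 and 20 for day 4 versus day 1. Leaving out each animal gave, lowest to highest, 455 to 642 for day 1, 1545 to 3215 for day 3, 111 to 1819 for day 4, 1242 to 2801 for day 7, 288 to 1360 for day 8, 2638 to 3229 for day 10, 1171 to 2127 for day 14, 2831 to 4177 for day 17, 3428 to 4542 for day 21, 0 to 185 for day 4 versus day 3, 145 to 2828 for day 8 versus day 7, 0 to 21 for day 4 versus day 1, 3 to 9 for day 8 versus day 1, 0 to 1522 for the third against the first dose, 0 to 2 for sex by day and 10 to 14 for sex at day 0. Of 46 gene-set scores, library totals moved 7 across the threshold and upper-quartile factors 2, and RLE factors and the lower prior count 0. None of these scores and no correlation past the threshold reversed under the settings run. The same held for called values of the 4 identifiers for day 1 versus day 0, day 4 versus day 3 and day 8 versus day 7. Leaving out single animals took 6 of 24 correlations (unadjusted exact p) and 7 of 96 identifier values from past the threshold to short of it. The identifiers' other comparisons with day 0 and the means of dose-called sets by day were not checked under other settings.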

Other observations

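Both hypotheses in this part were tested after related values had been seen. Over the 9 later days, 7903 of the 16054 genes were called against day 0 at least 1 time and 8151 on no day. Of the former, 3847 were called only up, 3636 only down, and 420 up on some days and down on others. On all 9 days, 8 genes were called up and 14 down. After the first dose 105 of the 298 falling genes were called up on day 21 and 88 called down, where independent lists would share 37.3 and 45.2. The shared day 0 libraries raise the second of these numbers and lower the first.

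One hypothesis is that the genes called down 24 h after the second dose later rise above their level before dosing. It was examined on the 29 genes called down between days 3 and 4, on days not used to choose them. The day 7 value is the one already given above, so it is no separate test. Their mean log2 difference from day 0 was 0.89 ± 0.37 (SD, n = 8) on day 7, with 8 of 8 animals above day 0 (exact permutation p = 0.00781, the smallest possible, adjusted p = 0.0164). The larger set that fell after the first dose gave no such call in the animals left out, at 0.13 on day 7, -0.02 on day 10, 0.05 on day 17 and 0.00 on day 21 (exact adjusted p = 0.159, 0.819, 0.668 and 1). For the 29 genes the course would be consistent with cells that leave the blood and return in larger numbers, but no cell counts were analysed here, the genes are not named, and transcription within cells could give the same course.

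A further hypothesis is that the late profile was already forming before the third dose and was interrupted by it. In animals left out of choosing the genes, the set higher on day 21 changed by -0.43 ± 0.30 from day 7 to day 8, in 8 of 8 animals, and by 0.43 ± 0.26 from day 8 to day 10, again in 8 of 8 (exact adjusted p = 0.0216 for each). It also changed by -0.23 ± 0.27 from day 3 to day 4 in 8 of 8 animals (exact adjusted p = 0.0216), or by -0.14 without animal 39102, while the set lower on day 21 changed by 0.26 ± 0.43, with 6 of 8 animals higher (exact adjusted p = 0.0536), or by 0.12 without animal 39102. The higher set changed by -0.08 ± 0.12 from day 0 to day 1, with 5 of 8 lower (exact adjusted p = 0.159). The fall and return would go with a late profile interrupted after the third dose. However, the step from day 7 to day 8 restates the means given above and is no separate test. Mean TMM factors moved alike, at 1.083 on day 7, 0.841 on day 8 and 1.013 on day 10. TMM factors followed the main axis of variation among libraries (19.4% of the variance) with a Spearman correlation of 0.95. Whether the dip reflects that axis was not tested, and elapsed time without the drug was not measured.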
